A study of Homo sapiens with 12 samples.

How the data were processed

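RNA was profiled on 12 Affymetrix oligonucleotide arrays, each with 54675 probe sets, a probe set being a group of short probes read together as 1 value. The samples were MCF-10A cells, an established non-tumorigenic human mammary epithelial line, collected 48 h after retroviral infection. Per the labels, 4 groups of 3 biological replicates received an empty vector, full-length NOTCH1, a NOTCH1 with the L1601P and ΔP changes, or NICD. NICD is the free intracellular domain of NOTCH1. The descriptions of those samples add gfp to its name, and whether that means a fused tag, a separate reporter or neither is not given in the sources used here. L1601P lies in the domain that holds the receptor's subunits together, and ΔP removes the C-terminal PEST region that limits the stability of the intracellular domain. The labels call the replicates biological and say nothing further about how separately they were cultured and infected, so p-values measure the spread between these samples.

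The values used are the authors' deposited log2 signals. Per the submitters' processing notes, RMA (background correction, quantile normalization and probe set summary) and limma were used. Their versions are not given in the sources used here. The deposited log2 values ran from 2.27 to 15.01 on the 12 arrays, with array medians between 5.64 and 5.697. Quantile normalization gives all arrays nearly the same distribution, so a shift of most genes in one direction cannot be seen in such values. No scanner file was used here, and the dimmest signals are compressed by the summary, so folds against a level near 3 or 4 on the log2 scale understate the change. Depth has no counterpart on these arrays, whose number limits the precision.

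Gene names came from the platform annotation, with symbols checked against current RefSeq gene numbers. Of the 54675 probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none in that annotation, and 62 were Affymetrix controls. Of those with 1 symbol, 41037 matched a RefSeq gene number and 54 did not. No symbol had to be changed. Tests used 1 probe set per gene, the one with the highest mean over the 12 arrays, which gave 19775 genes, 10523 of them with several probe sets. The 13522 probe sets with several symbols or none were tested apart.

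The comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) on the log2 values, with group means as the only terms and all 12 arrays in 1 fit. That left 8 residual degrees of freedom, to which the moderation added 4.09. Each of the 3 Notch1 groups was compared with vector, and the Notch1 groups with each other, 6 comparisons in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested within a comparison. Tests were two-sided. Errors are the SD over 3 arrays for group means and the standard error of the fit for log2 fold changes.

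The rule for naming genes, the gene lists, the main tests and most of their alternatives were fixed before the data were examined. NOTCH1 is given first, with each of its probe sets. In each comparison with vector, the 10 genes with the largest rise and the 10 with the largest fall were named, and between Notch1 groups the 6 largest in each direction. They were taken from the called genes whose arrays did not overlap between the groups. Chance alone separates 3 arrays from 3 in 10% of genes. Genes with opposite calls were named up to the 10 with the largest difference. Under each list, 2 to 4 called members per direction with the largest changes could be named, and any member of the Notch lists. For some lists 1 such member is given, and a member already named in the same comparison is not always repeated. A gene named outside this rule is said to be so where it appears.

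The 21 lists cover Notch target genes; Notch receptors, ligands and pathway components; DNA replication; mitosis; cyclin-dependent kinase inhibitors and growth arrest; p53 target genes; basal and myoepithelial markers; luminal markers; epithelial junctions; mesenchymal and EMT (epithelial-mesenchymal transition) markers; integrins, laminins and matrix adhesion; keratinocyte differentiation; the type I interferon response; inflammatory cytokines and NF-kB targets; EGFR ligands and MAPK feedback genes; TGF-beta and YAP target genes; the unfolded protein and amino acid stress response; cholesterol and fatty acid synthesis; hypoxia and glycolysis; ribosome biogenesis and MYC target genes; and markers of fibroblasts, endothelium and blood cells. They hold 515 genes, of which 473 were tested and 42 were not analysed here. Lists share some members. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 21 lists of a comparison. It was tested again with a correlation estimated from the data for each list, for which camera also uses the residual degrees of freedom of the fit in place of the number of genes. Calls within a list are also given adjusted over the list alone.

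Genes called in both of a pair of comparisons were set against n1 × n2 / N per direction, the overlap of independent lists. The correlation and covariance of their log2 fold changes were set against 100 simulations of unchanged groups compared with the same vector arrays, since comparisons with the same controls share their chance values. These simulations take genes as independent, so 100 random rotations of the arrays' own deviations from their group means, which keep the correlation between genes, were added after the results were seen. The 3 vector arrays are too few to give each comparison 2 of its own, so the part of any excess that comes from the shared controls was not measured apart.

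The fit was tested on simulated data with the vector levels and the pooled within-group spreads of all 19775 genes, each gene drawn independently. The 3 Notch1 groups were simulated alike, each with its own random set of changed genes. For simulated NICD against vector, 30% of genes changed by 0.25 on the log2 scale were recovered, 78.9% at 0.5 and 100% at 1. For simulated full-length Notch1 against vector the shares were 32%, 80.3% and 98%. For simulated Notch1 L1601P+ΔP against vector they were 14%, 74.6% and 98%. At 0.25, 15, 16 and 7 of 50 genes were recovered in that order, a difference that comes from the random draw. Among unchanged genes, 8 were called for simulated NICD and 10 for each of the others, and no call had the wrong direction. In these 3 simulated comparisons, the 1 list given a shift was called and 0 others were. That list was given the same shift in all 3 Notch1 groups, and in the 3 comparisons between them 0 lists were called. The recovery of a list shift between Notch1 groups was therefore not tested. As the simulated genes were independent, false list calls that arise from correlated genes were not tested either. In the real data the estimated correlation reached 0.4, for the mitosis list.

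Alternatives were a filter on dim genes, the mean of a gene's probe sets, all probe sets, only the 6 arrays of the groups compared, the replicate number as a block, median centring, cyclic loess between arrays, a variance trend with robust moderation, array weights, the estimated correlation for lists, and leaving out each array in turn. The dim filter left out genes with a mean below 5.67, the median of all probe set means, and kept 12572 genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

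Arrays were compared before averaging. No array was a copy of another, and correlations were 0.997 to 0.9985 within groups and 0.9825 to 0.9985 between groups. The labels and values gave no scan date or batch that could be used as a term.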

Results

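Messenger RNA was measured in MCF-10A cells, a non-tumorigenic human mammary epithelial line, 48 h after retroviral infection. Of 4 groups with 3 arrays each, 1 carried the empty vector, and the others carried full-length NOTCH1, Notch1 L1601P+ΔP or NICD, the free intracellular domain. Array medians of the deposited log2 signal lay between 5.64 and 5.697, and the number of arrays limits the precision. The first principal component held 69.65% of the variance and set the NICD arrays (38.4 to 41.5) apart from the rest. On it the Notch1 L1601P+ΔP arrays (-2.7 to -1.3) lay between NICD and the vector and full-length Notch1 arrays (-21.1 to -17.1). The difference between 3′ and 5′ control probe sets, a sign of RNA integrity, was -0.04 ± 0.02 for GAPDH with NICD and -0.01 ± 0.01 with vector. For ACTB it was 0.39 ± 0.05 with NICD and 0.30 ± 0.05 with vector. Group means below are log2 signals ± SD and differences are log2 fold changes ± standard error, with n = 3 arrays per group throughout.

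NOTCH1, the receptor introduced, was read by 2 probe sets that behaved differently. The dimmer one rose from 6.54 ± 0.20 with vector to 9.16 ± 0.04 with full-length Notch1, 8.74 ± 0.02 with Notch1 L1601P+ΔP and 8.79 ± 0.04 with NICD. The adjusted p over all probe sets was 1.23e-08, 1.37e-08 and 7.92e-10 in that order. Against full-length Notch1, this probe set was lower by 0.42 ± 0.08 with Notch1 L1601P+ΔP and by 0.37 ± 0.08 with NICD. The limma adjusted p over all probe sets was 0.0268 and 0.008. The brighter one stood at 9.44 ± 0.06 with vector and rose by 0.28 ± 0.06 with NICD (adjusted p = 0.00881 over all probe sets). Its differences of 0.08 with full-length Notch1 and 0.06 with Notch1 L1601P+ΔP were not called. The gene-level tests used the brighter one, and which part of the transcript each probe set reads was not analysed here.

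RAP1A, a small GTPase, was lower with every Notch1 form on its brightest probe set, and its other probe sets were listed after the values were seen. The brightest stood at 13.37 ± 0.06 with vector, 12.21 ± 0.06 with full-length Notch1, 11.80 ± 0.03 with Notch1 L1601P+ΔP and 11.28 ± 0.06 with NICD. The next differed by -1.44, -1.87 and -2.42 in the same order. The remaining RAP1A probe sets were not called in any comparison with vector. The one at 10.60 ± 0.10 with vector differed by 0.06, 0.11 and 0.14, and the one at 6.90 ± 0.02 by 0.09, -0.11 and 0.08. The latter was higher by 0.19 with NICD than with Notch1 L1601P+ΔP (limma adjusted p = 0.0318 over all probe sets).

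**Figure D1:**
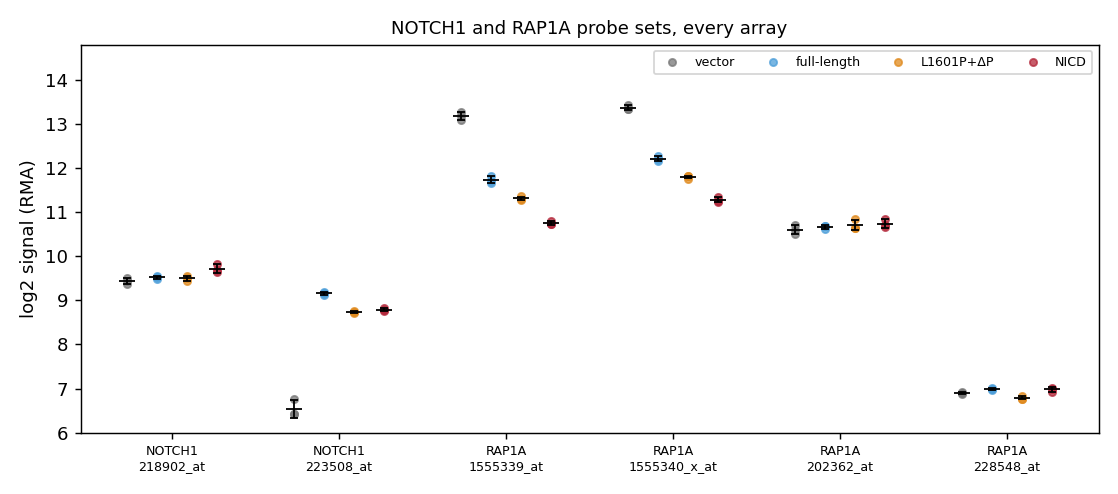
Log2 signal of the 2 NOTCH1 and 4 RAP1A probe sets (vertical axis) in the 4 groups, with 1 point per array and bars for the mean ± SD of 3 arrays. The dimmer NOTCH1 probe set lies higher with each Notch1 form than with vector, and 2 RAP1A probe sets lie lower.

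**Figure D2:**
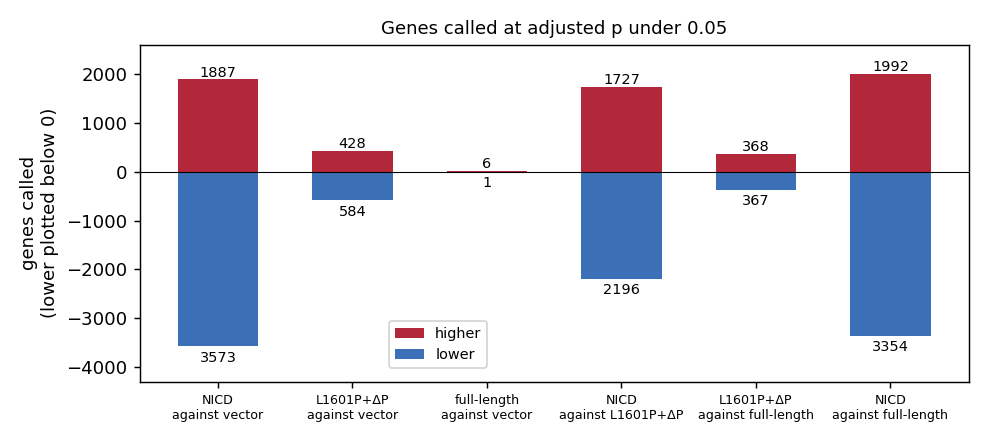
Number of genes called at an adjusted p under 0.05 in each of the 6 comparisons (vertical axis), with bars above 0 for genes higher and below 0 for genes lower in the group named first. NICD against vector gave 1887 higher and 3573 lower, and full-length Notch1 against vector 6 and 1.

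NICD against vector asks what the active intracellular domain changes in these cells, and any part of its difference that comes from a GFP in the construct was not analysed here. OLFM4, a secreted glycoprotein known from intestinal crypts, rose from 3.62 ± 0.27 to 13.43 ± 0.06, or 9.81 ± 0.13 on the log2 scale (adjusted p = 7.47e-14). PLA2G2A, a secreted phospholipase, rose from 6.83 ± 0.11 to 14.48 ± 0.02 (adjusted p = 7.23e-15). CHI3L2, a chitinase-like protein, rose from 6.03 ± 0.17 to 13.56 ± 0.09 (adjusted p = 7.47e-14). The largest fall was that of COL8A1, a collagen chain, from 8.85 ± 0.05 to 6.0 ± 0.12 (adjusted p = 1.03e-11). KRT15, a keratin of basal epithelial cells, fell from 12.50 ± 0.04 to 9.96 ± 0.04 (adjusted p = 4.12e-12).

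The other largest rises with NICD were those of the chemokine CXCL14 (6.93 ± 0.12), IGFBP7-AS1 (6.41 ± 0.11), the GABA-A receptor subunit GABRP (6.25 ± 0.13) and the atypical chemokine receptor ACKR3 (6.22 ± 0.11). They were followed by FDCSP (6.0 ± 0.10), LBH (5.96 ± 0.19) and CCDC102B (5.75 ± 0.13). The other largest falls were those of KLRC3 (-2.67 ± 0.07), the forkhead factor FOXQ1 (-2.65 ± 0.07), TPRG1 (-2.54 ± 0.11) and AOX1 (-2.49 ± 0.05). SVEP1 (-2.34 ± 0.06), the receptor tyrosine kinase AXL (-2.26 ± 0.08), PSCA (-2.25 ± 0.10) and LNCAROD (-2.20 ± 0.14) came next. The size depended on the probe set for some genes, as for ACKR3, whose 3 probe sets rose by 0.26 to 6.22. For COL8A1, 2 of 3 probe sets were called, with values from -2.85 to -0.09, and for SVEP1 6 of 7, from -2.37 to -0.13.

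Of 22 Notch target genes, 12 rose and 5 fell with NICD, and 13 and 6 were called when adjusted over the list alone. NRARP, a feedback regulator of Notch signalling, rose by 4.43 ± 0.10. The transcriptional repressors HEY2 and HEY1 rose by 3.69 ± 0.08 and 3.35 ± 0.06, and the ligand JAG1 by 2.32 ± 0.06. LFNG, which glycosylates Notch receptors, fell by 1.58 ± 0.10. HES1 was not called (0.16 ± 0.09, adjusted p = 0.231). As a group the targets were higher than other genes (adjusted p = 2.76e-05), also with an estimated correlation (adjusted p = 0.0366). Among 31 Notch receptors, ligands and pathway components, 5 rose and 9 fell, 6 and 9 adjusted over the list alone. DLK2 fell by 1.89 ± 0.07 and JAG2 by 1.5 ± 0.09, and the list was not shifted (adjusted p = 0.82).

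**Figure D3:**
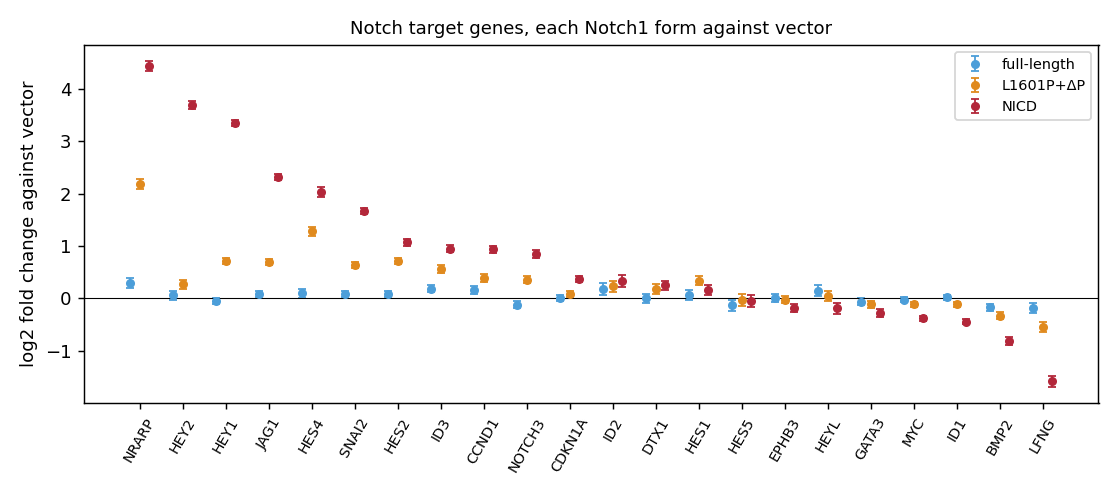
Log2 fold change against vector (vertical axis) of 22 Notch target genes for full-length Notch1, Notch1 L1601P+ΔP and NICD, with points for the difference of the means of 3 arrays and bars for its standard error. NRARP differed by 4.43 with NICD and by 2.18 with Notch1 L1601P+ΔP.

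Of 27 mesenchymal and EMT markers, 11 rose and 5 fell with NICD, 12 and 5 adjusted over the list alone. The matrix proteins FBN1 and SPARC rose by 3.4 ± 0.09 and 2.45 ± 0.08, and the repressor ZEB2 by 2.36 ± 0.15. The matrix cross-linking enzyme LOX fell by 0.71 ± 0.06. Together its members were higher than other genes (adjusted p = 0.000246), but not with an estimated correlation (adjusted p = 0.0875 with an estimated correlation). Of 16 markers of fibroblasts, endothelium and blood cells, 4 rose and 0 fell by limma (5 higher and 0 lower at an unadjusted p under 0.05), the same numbers adjusted over the list alone. POSTN rose from 3.83 ± 0.20 to 8.21 ± 0.09, CD14 by 2.59 ± 0.06, KDR by 1.05 ± 0.09 and DCN by 0.36 ± 0.05. That list was higher by camera (adjusted p = 0.000575), also with an estimated correlation (adjusted p = 0.0366). Its median was 0.10 and its mean 0.57, and 12 of its 16 members were not called, so few members carried the shift.

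Of 19 basal and myoepithelial markers, 3 rose and 7 fell with NICD, the same adjusted over the list alone. KRT5 rose by 0.58 ± 0.05 and KRT14 by 0.57 ± 0.07, while the integrin ITGB4 fell by 1.97 ± 0.06 and the plakin DST fell by 1.82 ± 0.08. Of 25 luminal markers, 3 rose and 8 fell, 4 and 8 adjusted over the list alone. TFF1 rose by 1.28 ± 0.11, AGR2 fell by 1.26 ± 0.15 and the pioneer factor FOXA1 fell by 1.09 ± 0.11. Of 27 epithelial junction genes, 8 rose and 7 fell, 9 and 9 adjusted over the list alone. DSC3 rose by 0.98 ± 0.07 and PKP2, both parts of desmosomes, fell by 1.41 ± 0.07. None of these lists was shifted (adjusted p = 0.0563, 0.765 and 0.234), and the luminal median of 0.02 and mean of -0.08 differed in sign.

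Of 26 integrins, laminins and matrix adhesion genes, 7 rose and 14 fell with NICD, 7 and 15 adjusted over the list alone. COL4A1 rose by 1.56 ± 0.06 and ITGA5 by 1.16 ± 0.07, while LAMB3 fell by 1.44 ± 0.05 and THBS1 fell by 1.21 ± 0.09. Of 26 keratinocyte differentiation genes, 9 rose and 8 fell, 10 and 9 adjusted over the list alone. The envelope protein IVL rose by 3.25 ± 0.10 and S100A7 by 2.80 ± 0.18, and PPL fell by 0.89 ± 0.07. Of 19 TGF-beta and YAP target genes, 7 rose and 8 fell, 7 and 9 adjusted over the list alone. The matricellular protein CCN1 rose by 3.22 ± 0.07 and AJUBA fell by 1.62 ± 0.06. None of the 3 lists was shifted (adjusted p = 0.0616, 0.0603 and 0.689).

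Of 25 inflammatory cytokines and NF-kB targets, 12 rose and 4 fell with NICD, 13 and 5 adjusted over the list alone. The cytokine IL6 rose by 3.57 ± 0.09 and TNFAIP3, an inhibitor of NF-kB signalling, by 1.88 ± 0.06, while CSF3 fell by 1.17 ± 0.09. The list was higher (adjusted p = 0.00338), but not with an estimated correlation (adjusted p = 0.213 with an estimated correlation). Of 21 EGFR ligands and MAPK feedback genes, 3 rose and 14 fell, 4 and 14 adjusted over the list alone. The ligand EREG fell by 1.23 ± 0.07, EPHA2 by 1.05 ± 0.06 and SPRED2 by 1.0 ± 0.05, while CCND1 rose by 0.94 ± 0.07. The list was lower (adjusted p = 0.000147; adjusted p = 0.103 with an estimated correlation). Of 28 type I interferon genes, 7 rose and 6 fell, 8 and 9 adjusted over the list alone. ISG20 rose by 1.19 ± 0.10 and IFI44L fell by 1.77 ± 0.10. The interferon list was not shifted (adjusted p = 0.79), and its median of 0.03 and mean of -0.07 differed in sign.

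Of 21 cholesterol and fatty acid synthesis genes, 1 rose and 16 fell with NICD, 1 and 18 adjusted over the list alone. The desaturase SCD fell by 0.76 ± 0.05, the regulator SREBF1 by 0.74 ± 0.08 and ACACA by 0.71 ± 0.05, while LSS rose by 0.31 ± 0.05. The list was lower (adjusted p = 3.89e-06), but not with an estimated correlation (adjusted p = 0.0875 with an estimated correlation). Of 20 ribosome biogenesis and MYC target genes, 0 rose by limma and 9 fell (0 and 13 at an unadjusted p under 0.05), 0 and 12 adjusted over the list alone. ODC1, which makes polyamines, fell by 0.75 ± 0.05, SRM, a spermidine synthase, by 0.30 ± 0.08 and CAD by 0.28. The SRM call was lost under 5 alternatives, among them cyclic loess and leaving out NICD replicate 1 or 3, with a highest adjusted p of 0.0765. The group as a whole was lower (adjusted p = 0.00576; adjusted p = 0.369 with an estimated correlation), and the call ended without dim genes (adjusted p = 0.052) and after cyclic loess (adjusted p = 0.0567). Of 25 unfolded protein and amino acid stress genes, 3 rose and 10 fell, the same adjusted over the list alone. The cystine transporter SLC7A11 fell by 1.75 ± 0.19 and TRIB3 by 1.20 ± 0.14. Of 21 hypoxia and glycolysis genes, 5 rose and 5 fell, also adjusted over the list alone, with EGLN3 at 1.56 ± 0.08 and ADM at -0.77 ± 0.09. Neither of the last 2 lists was shifted (adjusted p = 0.668 for both), and the hypoxia median of -0.01 and mean of 0.03 differed in sign.

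Of 15 cyclin-dependent kinase inhibitors and growth arrest genes, 8 rose and 2 fell with NICD, 9 and 4 adjusted over the list alone. The zinc finger factor KLF9 rose by 1.72 ± 0.11, GADD45A by 1.52 ± 0.05 and the inhibitor CDKN1C by 1.03 ± 0.10, while TXNIP fell by 0.84 ± 0.05. Together its members were higher (adjusted p = 0.00717; adjusted p = 0.195 with an estimated correlation). Of 22 p53 target genes, 7 rose and 4 fell, also adjusted over the list alone, with the kinase PLK2 at 1.53 ± 0.06 and GDF15 at -1.03 ± 0.12. Of 31 DNA replication genes, 1 rose and 10 fell, also adjusted over the list alone, and GINS3 fell by 0.35. Of 30 mitosis genes, 1 rose and 1 fell, and 0 were called in either direction by limma when adjusted over the list alone (2 higher and 1 lower at an unadjusted p under 0.05). These 3 lists were not shifted (adjusted p = 0.107, 0.0603 and 0.926), and the mitosis test was upward while the list's median was -0.04 and its mean -0.02.

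In all, limma called 5460 of 19775 genes with NICD, 1887 higher and 3573 lower, with 354 at least 2-fold higher and 204 at least 2-fold lower. The arrays of both groups did not overlap in 39.1% of all genes, where chance gives 10%. The share of higher genes was 34.6%, and 51.6% after cyclic loess, so the balance of directions depended on the scaling. Of the 21 lists, 8 were shifted and 2 with an estimated correlation.

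Notch1 L1601P+ΔP against vector asks what a mutated receptor changes. PLA2G2A rose from 6.83 ± 0.11 to 13.47 ± 0.15 (adjusted p = 4.01e-14), and OLFM4 from 3.62 ± 0.27 to 10.18 ± 0.17 (adjusted p = 1.44e-11). CHI3L2 rose by 3.4 ± 0.10, SERPINB4 by 2.71 ± 0.11 and IGFL1 by 2.65 ± 0.11. The protease inhibitor SERPINA3 rose by 2.47 ± 0.06, HSD17B2, which oxidises estradiol, by 2.37 ± 0.08, CCDC102B by 2.30 ± 0.13, CCN1 by 2.29 ± 0.07 and LBH by 2.25 ± 0.19. Falls were smaller. RAP1A fell by 1.58 ± 0.06 on 1 of its probe sets, COL8A1 by 1.05 ± 0.07, KLRC3 by 0.96 ± 0.07 and GREB1 by 0.93 ± 0.08. ALDH3A1 (-0.80 ± 0.08), BLNK (-0.80 ± 0.11), XDH (-0.79 ± 0.09), TNNI2 (-0.79 ± 0.11), MAP7D2 (-0.78 ± 0.13) and AXL (-0.78 ± 0.08) also fell. Only 1 of 3 GREB1 probe sets was called, with values from -0.93 to 0.15, 1 of 2 for CCDC102B (0.20 to 2.30), 1 of 2 for AXL (-0.78 to -0.21) and 2 of 3 for COL8A1 (-1.15 to -0.17).

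Of the 22 Notch target genes, 9 rose and 2 fell with Notch1 L1601P+ΔP, 11 and 2 adjusted over the list alone. NRARP rose by 2.18 ± 0.10, HES4 by 1.28 ± 0.09, HEY1 by 0.72 ± 0.06 and JAG1 by 0.70 ± 0.06. HEY2 (0.27, adjusted p = 0.0739) and HES1 (0.34, adjusted p = 0.0569) were not called. The list was higher (adjusted p = 1.13e-07), also with an estimated correlation (adjusted p = 0.0192). Of the fibroblast, endothelial and blood cell markers, 2 rose and 0 fell by limma (2 and 0 at an unadjusted p under 0.05), also adjusted over the list alone. POSTN rose by 2.07 ± 0.10 and CD14 by 0.86 ± 0.06. By camera the list was higher (adjusted p = 0.000454, and 0.031 with an estimated correlation), with a median of 0.10 and a mean of 0.25.

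Of 26 keratinocyte differentiation genes, 5 rose and 0 fell by limma with Notch1 L1601P+ΔP (12 and 1 at an unadjusted p under 0.05), 10 and 1 adjusted over the list alone. The elastase inhibitor PI3 rose by 1.91 ± 0.06 and IVL by 0.83 ± 0.10, and the list was higher (adjusted p = 1.13e-07; adjusted p = 0.216 with an estimated correlation). Of the junction genes, 6 rose and 3 fell, 9 and 3 adjusted over the list alone. DSG3 rose by 0.50 ± 0.05 and CLDN1 by 0.44 ± 0.05, and the list was higher (adjusted p = 0.00413; adjusted p = 0.23 with an estimated correlation). Of the mesenchymal and EMT markers, 4 rose and 1 fell, 5 and 2 adjusted over the list alone. ZEB2 rose by 0.93 ± 0.15 and FBN1 by 0.87 ± 0.09, and the list was higher (adjusted p = 0.00125; adjusted p = 0.155 with an estimated correlation). Of the inflammatory genes, 5 rose and 2 fell, 8 and 3 adjusted over the list alone. IL1B rose by 0.80 ± 0.08 and CCL20 by 0.53 ± 0.07, and the list was higher (adjusted p = 0.00742; adjusted p = 0.263 with an estimated correlation).

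Of the integrins, laminins and matrix adhesion genes, 1 rose and 7 fell with Notch1 L1601P+ΔP, 2 and 11 adjusted over the list alone. ITGB4 fell by 0.61 ± 0.06 and LAMB3 by 0.38 ± 0.05, and the list was lower (adjusted p = 0.000331; adjusted p = 0.146 with an estimated correlation). Of the EGFR ligands and MAPK feedback genes, 1 rose and 5 fell, 2 and 8 adjusted over the list alone, and SPRED2 fell by 0.44 ± 0.05. As a list they were lower (adjusted p = 0.00713; adjusted p = 0.23 with an estimated correlation), and the call ended without dim genes (adjusted p = 0.102) and after cyclic loess (adjusted p = 0.0595). The DNA replication list was lower (median -0.10, adjusted p = 0.000474; adjusted p = 0.294 with an estimated correlation), a call that ended after cyclic loess (adjusted p = 0.0527). limma called 0 of its 31 members, also adjusted over the list alone, and 7 were lower at an unadjusted p under 0.05.

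In all, limma called 1012 genes with Notch1 L1601P+ΔP, 428 higher and 584 lower, and 4132 genes had an unadjusted p under 0.05. The count was 592 without vector replicate 3, 628 without Notch1 L1601P+ΔP replicate 1 and 566 without its replicate 2. It was 1616 with a variance trend and robust moderation and 1638 with array weights. The share of higher genes was 42.3%, and 58.4% after cyclic loess. Of the 21 lists, 9 were shifted and 2 with an estimated correlation.

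Full-length Notch1 against vector asks what the intact receptor changes. PLA2G2A rose from 6.83 ± 0.11 to 10.08 ± 0.01 (adjusted p = 2.18e-10) and OLFM4 from 3.62 ± 0.27 to 5.86 ± 0.16 (adjusted p = 3.48e-06). RAP1A fell by 1.17 ± 0.06 on 1 of its probe sets (adjusted p = 7.51e-07). HSD17B2 rose by 0.59 ± 0.08, SERPINA3 by 0.55 ± 0.06, CCN1 by 0.53 ± 0.07 and PDIA4, a disulfide isomerase of the endoplasmic reticulum, by 0.44 ± 0.05. Adjusted over all probe sets, no probe set of HSD17B2, CCN1 or PDIA4 was called. The calls of these 4 genes ended when only the 6 arrays of both groups were fitted, with adjusted p = 0.507, 0.178, 0.115 and 0.115. With the replicate number as a block, the adjusted p was 0.063 for HSD17B2, 0.106 for CCN1 and 0.063 for PDIA4, and leaving out 1 array also ended the calls of these 3. For HSD17B2 the adjusted p was 0.0527, 0.0521 and 0.0693 without vector replicates 1, 2 and 3, and 0.112 and 0.135 without full-length Notch1 replicates 2 and 3. For CCN1 it was 0.155 and 0.153 without vector replicates 1 and 3, 0.0944, 0.112 and 0.146 without full-length Notch1 replicates 1, 2 and 3, and 0.0501 after cyclic loess. For PDIA4 it was 0.0728 and 0.0669 without vector replicates 1 and 2, and 0.0859, 0.0545 and 0.09 without full-length Notch1 replicates 1, 2 and 3.

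Of the 22 Notch target genes, limma called 0 with full-length Notch1 (3 higher and 1 lower at an unadjusted p under 0.05), also adjusted over the list alone, and the list was not shifted (median 0.04, adjusted p = 0.116). Of 25 unfolded protein and amino acid stress genes, PDIA4 rose, and 7 rose when adjusted over the list alone. The chaperones HSP90B1 and HSPA5, chosen after their values were seen, differed by 0.28 ± 0.05 and 0.26 ± 0.05 (adjusted p = 0.223 and 0.238 over all genes). Together its members were higher (median 0.09, adjusted p = 7e-08; adjusted p = 0.276 with an estimated correlation). Of 26 keratinocyte genes, 0 were called by limma (8 higher and 0 lower at an unadjusted p under 0.05) and 3 rose adjusted over the list alone. The list was higher (median 0.13, adjusted p = 1.7e-09; adjusted p = 0.276 with an estimated correlation). Of 28 interferon genes, limma called 0 (1 higher and 6 lower at an unadjusted p under 0.05), also adjusted over the list alone, and the list was lower (median -0.09, adjusted p = 0.00182; adjusted p = 0.338 with an estimated correlation).

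The junction list was higher with full-length Notch1 (median 0.05, adjusted p = 0.0072; adjusted p = 0.338 with an estimated correlation), and limma called 0 of its members (2 higher and 0 lower at an unadjusted p under 0.05), also adjusted over the list alone. Its call ended after cyclic loess (adjusted p = 0.0549), without vector replicate 3 (0.0584) and without full-length Notch1 replicates 2 (0.0915) and 3 (0.0601). The cholesterol list was higher (median 0.03, adjusted p = 0.0225; adjusted p = 0.391 with an estimated correlation), with 0 members called by limma (1 higher and 0 lower at an unadjusted p under 0.05), also adjusted over the list alone. Its call ended after cyclic loess (adjusted p = 0.177), without vector replicates 1 (0.0587) and 2 (0.188) and without full-length Notch1 replicates 2 (0.106) and 3 (0.0749). The vector and full-length Notch1 arrays did not overlap in 11% of all genes, where chance gives 10%. Unchanged genes pass an unadjusted p under 0.05 at a rate of 0.05, and 1053 of 19775 genes passed it here by limma. In all, limma called 7 genes with full-length Notch1. The count was 4 without vector replicate 1 or full-length Notch1 replicate 2 or 3, 3 with only the 6 arrays of both groups, and 4 with the replicate block. It was 19 with a variance trend and robust moderation. Of the 21 lists, 5 were shifted, 0 with an estimated correlation, and 3 after cyclic loess or without full-length Notch1 replicate 2 or 3.

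NICD against Notch1 L1601P+ΔP asks how both activated forms differ. ACKR3 was at 9.69 ± 0.17 with NICD and 3.70 ± 0.12 with Notch1 L1601P+ΔP (adjusted p = 4.27e-12). GABRP was higher by 5.92 ± 0.13, FDCSP by 5.60 ± 0.10, IGFBP7-AS1 by 5.12 ± 0.11, CXCL14 by 5.02 ± 0.12 and DAPL1 by 4.62 ± 0.11. KRT15 was at 9.96 ± 0.04 with NICD and 12.14 ± 0.09 with Notch1 L1601P+ΔP (adjusted p = 4.74e-11). FOXQ1 (-2.02 ± 0.07), PSCA (-1.98 ± 0.10), TPRG1 (-1.83 ± 0.11), AOX1 (-1.83 ± 0.05) and COL8A1 (-1.80 ± 0.07) were also lower. For ACKR3 2 of 3 probe sets were called (0.15 to 5.99), and for COL8A1 2 of 3 (-1.80 to 0.08).

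Of the Notch target genes, 11 were higher and 4 lower with NICD than with Notch1 L1601P+ΔP, 11 and 6 adjusted over the list alone. HEY2 was higher by 3.42 ± 0.08 and HEY1 by 2.63 ± 0.06, and the list was higher (adjusted p = 0.000662; adjusted p = 0.0734 with an estimated correlation). Of the mesenchymal and EMT markers, 10 were higher and 3 lower, also adjusted over the list alone. FBN1 was higher by 2.52 ± 0.09 and SPARC by 2.28 ± 0.08, and the list was higher (adjusted p = 0.00338; adjusted p = 0.124 with an estimated correlation). Of the growth arrest genes, 7 were higher and 2 lower, 8 and 3 adjusted over the list alone. KLF9 was higher by 1.81 ± 0.11, and the list was higher (adjusted p = 0.00696; adjusted p = 0.175 with an estimated correlation). Of the p53 target genes, 7 were higher and 4 lower, 9 and 4 adjusted over the list alone, with GADD45A higher by 0.77 ± 0.05 and PLK2 by 0.67. That list was higher (adjusted p = 0.0139; adjusted p = 0.306 with an estimated correlation), not with the mean of a gene's probe sets (adjusted p = 0.0998).

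Of the inflammatory genes, 7 were higher and 4 lower with NICD than with Notch1 L1601P+ΔP, 11 and 4 adjusted over the list alone. IL6 was higher by 3.34 ± 0.09, and the list was higher (adjusted p = 0.0139; adjusted p = 0.312 with an estimated correlation), not without dim genes (adjusted p = 0.058). Of the fibroblast, endothelial and blood cell markers, 4 were higher and 0 lower by limma (4 and 0 at an unadjusted p under 0.05), also adjusted over the list alone, with POSTN higher by 2.30 ± 0.10. That list was higher by camera (adjusted p = 0.0105, and 0.0734 with an estimated correlation), not without dim genes (adjusted p = 0.193). Its median was 0.05 and its mean 0.32. Of the cholesterol genes, 1 was higher and 14 lower, 1 and 17 adjusted over the list alone. HMGCS1, which makes a precursor of mevalonate, differed by -0.86 ± 0.25, SCD by -0.65 ± 0.05 and ACACA by -0.58 ± 0.05. The HMGCS1 call was lost with only the 6 arrays of both groups, with a variance trend and robust moderation, and without Notch1 L1601P+ΔP replicate 1 or 2 or NICD replicate 3, with a highest adjusted p of 0.0835. Together the cholesterol genes were lower (adjusted p = 1.45e-06; adjusted p = 0.0734 with an estimated correlation). Of the EGFR ligands and MAPK feedback genes, 3 were higher and 13 lower, 3 and 14 adjusted over the list alone. EPHA2 differed by -0.85 ± 0.06, and the list was lower (adjusted p = 0.000236; adjusted p = 0.105 with an estimated correlation).

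Of the basal markers, 2 were higher and 7 lower with NICD than with Notch1 L1601P+ΔP, 3 and 7 adjusted over the list alone. Besides KRT15, DST differed by -1.36 ± 0.08 and ITGB4 by -1.36 ± 0.06, and the list was lower (adjusted p = 0.00696; adjusted p = 0.0734 with an estimated correlation), not with the mean of a gene's probe sets (adjusted p = 0.139). Of the ribosome and MYC genes, 0 were higher by limma and 4 lower (0 and 9 at an unadjusted p under 0.05), 0 and 5 adjusted over the list alone, with ODC1 at -0.45 ± 0.05. That list was lower (adjusted p = 0.02; adjusted p = 0.499 with an estimated correlation), not after cyclic loess (adjusted p = 0.0919) or without NICD replicate 3 (adjusted p = 0.0632). In all, limma called 3923 genes, 1727 higher and 2196 lower. After cyclic loess 2114 were higher and 1865 lower, so the direction of the majority depended on the scaling. Of the 21 lists, 10 were shifted and 0 with an estimated correlation.

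Notch1 L1601P+ΔP against full-length Notch1 asks what the receptor's changes add. Any part of the difference that comes from an unequal amount of NOTCH1 RNA was not analysed here. OLFM4 was higher by 4.32 ± 0.13 (adjusted p = 2.19e-09) and PLA2G2A by 3.38 ± 0.07 (adjusted p = 1.34e-10). CHI3L2 was higher by 2.98 ± 0.10, CCDC102B by 2.47 ± 0.13, SERPINB4 by 2.30 ± 0.11 and IGFL1 by 2.30 ± 0.11. GREB1 was lower (-0.93 ± 0.08, adjusted p = 3.02e-05), as were COL8A1 (-0.86 ± 0.07), MAP7D2 (-0.78 ± 0.13), TNNI2 (-0.76 ± 0.11) and ALDH3A1 (-0.75 ± 0.08). AGR2 was lower as well (-0.70 ± 0.15, adjusted p = 0.0259), with 1 of its 2 probe sets called (-0.70 to -0.06). For GREB1 1 of 3 probe sets was called (-0.93 to 0.01), for CCDC102B 1 of 2 (0.18 to 2.47) and for COL8A1 2 of 3 (-0.88 to -0.10). The AGR2 call ended without full-length Notch1 replicates 1, 2 and 3 (adjusted p = 0.0716, 0.0685 and 0.0792) and without Notch1 L1601P+ΔP replicates 2 and 3 (adjusted p = 0.108 and 0.0822).

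Of the Notch target genes, 8 were higher and 0 lower by limma with Notch1 L1601P+ΔP than with full-length Notch1 (11 and 2 at an unadjusted p under 0.05), 11 and 2 adjusted over the list alone. NRARP was higher by 1.87 ± 0.10 and HES4 by 1.18 ± 0.09, and the list was higher (adjusted p = 1e-06; adjusted p = 0.0257 with an estimated correlation). Of the fibroblast, endothelial and blood cell markers, 2 were higher and 0 lower by limma (3 and 0 at an unadjusted p under 0.05), also adjusted over the list alone. POSTN was higher by 2.11 ± 0.10. By camera the list was higher (adjusted p = 0.000941, and 0.0472 with an estimated correlation), with a median of 0.075 and a mean of 0.24. Of the inflammatory genes, 6 were higher and 0 lower by limma (9 and 1 at an unadjusted p under 0.05), 7 and 1 adjusted over the list alone. IL1B was higher by 0.79 ± 0.08, and the list was higher (adjusted p = 0.000231; adjusted p = 0.144 with an estimated correlation). Of the mesenchymal and EMT markers, 5 were higher and 0 lower by limma (7 and 2 at an unadjusted p under 0.05), 6 and 2 adjusted over the list alone, with FBN1 higher by 0.98 ± 0.09. Together its members were higher (adjusted p = 0.00249; adjusted p = 0.144 with an estimated correlation). Of the keratinocyte genes, 4 were higher and 0 lower by limma (7 and 3 at an unadjusted p under 0.05), 6 and 2 adjusted over the list alone, with PI3 higher by 1.67 ± 0.06. That list was higher (adjusted p = 0.011; adjusted p = 0.423 with an estimated correlation), not without full-length Notch1 replicate 1 (adjusted p = 0.0749) or Notch1 L1601P+ΔP replicate 1 or 2 (adjusted p = 0.179 and 0.0557).

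Among the lists lower with Notch1 L1601P+ΔP than with full-length Notch1, the DNA replication genes had 0 members higher by limma and 1 lower, 1 and 12 at an unadjusted p under 0.05, and 0 and 5 adjusted over the list alone (adjusted p = 4.45e-06; adjusted p = 0.15 with an estimated correlation). Of the integrins, laminins and matrix adhesion genes, 1 was higher and 5 lower, 1 and 9 adjusted over the list alone, with ITGB4 at -0.64 ± 0.06 (adjusted p = 0.000679 for the list; adjusted p = 0.144 with an estimated correlation). Of the cholesterol genes, limma called 0 (0 higher and 8 lower at an unadjusted p under 0.05), and 5 were lower adjusted over the list alone (adjusted p = 0.000731 for the list; adjusted p = 0.144 with an estimated correlation). Of the unfolded protein genes, 0 were higher by limma and 4 lower (0 and 6 at an unadjusted p under 0.05), 0 and 5 adjusted over the list alone, with PDIA4 at -0.37 ± 0.05, CRELD2 at -0.31 ± 0.05, HSP90B1 at -0.30 ± 0.05 and HSPA5 at -0.27 ± 0.05. The HSP90B1 call was lost with the mean of a gene's probe sets (adjusted p = 0.0772). The group as a whole was lower (adjusted p = 0.00314; adjusted p = 0.307 with an estimated correlation), not without Notch1 L1601P+ΔP replicate 2 (adjusted p = 0.102). Of the EGFR ligands and MAPK feedback genes, 0 were higher by limma and 4 lower (1 and 7 at an unadjusted p under 0.05), 1 and 7 adjusted over the list alone, with EREG at -0.44 ± 0.07. As a list they were lower (adjusted p = 0.00866; adjusted p = 0.203 with an estimated correlation), not without dim genes (0.097), after cyclic loess (0.133) or without Notch1 L1601P+ΔP replicate 2 (0.052).

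In all, limma called 735 genes between Notch1 L1601P+ΔP and full-length Notch1, 368 higher and 367 lower, and 3789 had an unadjusted p under 0.05. The count was 474 and 409 without full-length Notch1 replicates 2 and 3, 462 and 403 without Notch1 L1601P+ΔP replicates 1 and 2, 1256 with a variance trend and robust moderation, and 1371 with array weights. The share of higher genes was 50.1%, 31.5% after median centring and 62.5% after cyclic loess. Of the 21 lists, 10 were shifted and 2 with an estimated correlation.

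NICD against full-length Notch1 sets the free intracellular domain beside the intact receptor. OLFM4 was higher by 7.57 ± 0.13, CHI3L2 by 7.12 ± 0.10 and CXCL14 by 6.68 ± 0.12. IGFBP7-AS1 (6.44 ± 0.11), ACKR3 (6.27 ± 0.11) and FDCSP (6.26 ± 0.10) followed. KRT15 (-2.67 ± 0.06), COL8A1 (-2.66 ± 0.07), FOXQ1 (-2.62 ± 0.07), AOX1 (-2.46 ± 0.05), PSCA (-2.35 ± 0.10) and KLRC3 (-2.30 ± 0.07) were lower. For COL8A1 2 of 3 probe sets were called (-2.66 to -0.01), and the 3 of ACKR3 were higher by 0.22 to 6.27.

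Of the Notch target genes, 11 were higher and 6 lower with NICD than with full-length Notch1, 12 and 7 adjusted over the list alone. NRARP was higher by 4.12 ± 0.10, and the list was higher (adjusted p = 7.89e-05; adjusted p = 0.0413 with an estimated correlation). Of the fibroblast, endothelial and blood cell markers, 4 were higher and 0 lower by limma (4 and 0 at an unadjusted p under 0.05), also adjusted over the list alone. POSTN was higher by 4.41 ± 0.10. By camera the list was higher (adjusted p = 0.000657, and 0.0413 with an estimated correlation), with a median of 0.11 and a mean of 0.56. Of the mesenchymal and EMT markers, 11 were higher and 5 lower, 12 and 5 adjusted over the list alone, with FBN1 higher by 3.50 ± 0.09 (adjusted p = 0.000377 for the list; adjusted p = 0.0981 with an estimated correlation). Of the inflammatory genes, 13 were higher and 3 lower, 14 and 3 adjusted over the list alone, with IL6 higher by 3.63 ± 0.09 (adjusted p = 0.000463 for the list; adjusted p = 0.143 with an estimated correlation). Of the growth arrest genes, 7 were higher and 2 lower, also adjusted over the list alone, with KLF9 higher by 1.73 (adjusted p = 0.0117 for the list; adjusted p = 0.218 with an estimated correlation).

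Of the cholesterol genes, 1 was higher and 19 lower with NICD than with full-length Notch1, also adjusted over the list alone, with SCD at -0.83 ± 0.05 (adjusted p = 9.91e-08 for the list; adjusted p = 0.0529 with an estimated correlation). Of the EGFR ligands and MAPK feedback genes, 4 were higher and 15 lower, also adjusted over the list alone, with EREG at -1.24 ± 0.07 (adjusted p = 0.000137 for the list; adjusted p = 0.102 with an estimated correlation). Of the unfolded protein genes, 1 was higher and 15 lower, 1 and 16 adjusted over the list alone, with SLC7A11 at -1.65 ± 0.19 (adjusted p = 0.00372 for the list; adjusted p = 0.346 with an estimated correlation). Of the basal markers, 3 were higher and 7 lower, also adjusted over the list alone, with ITGB4 at -2.00 ± 0.06. That list was lower (adjusted p = 0.0289; adjusted p = 0.104 with an estimated correlation), not with the mean of a gene's probe sets (adjusted p = 0.162). Of the ribosome and MYC genes, 0 were higher by limma and 8 lower (0 and 12 at an unadjusted p under 0.05), also adjusted over the list alone, with ODC1 at -0.72 ± 0.05. The group as a whole was lower (adjusted p = 0.00299; adjusted p = 0.336 with an estimated correlation), not after cyclic loess (adjusted p = 0.0867). Of the DNA replication genes, 2 were higher and 9 lower, also adjusted over the list alone, with UHRF1 at -0.35 ± 0.05. As a list they were lower (adjusted p = 0.0107; adjusted p = 0.461 with an estimated correlation), not without dim genes (adjusted p = 0.0876) or after cyclic loess (adjusted p = 0.271). In all, limma called 5346 genes, 1992 higher and 3354 lower. The share of higher genes was 37.3%, and 52.9% after cyclic loess. Of the 21 lists, 11 were shifted and 2 with an estimated correlation.

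Set side by side, NICD and Notch1 L1601P+ΔP changed 884 genes in the same direction against vector, 358 higher and 526 lower. Independent lists would share 40.8 and 105.5. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.712, where the shared controls alone gave 0.5, and a covariance of 0.0578, where they gave 0.0038. Of the 1012 genes called with Notch1 L1601P+ΔP, 789 lay further from vector in the same direction with NICD, and 648 of these were also called between both forms. The shared count was 544 without vector replicate 3, 571 and 512 without Notch1 L1601P+ΔP replicates 1 and 2, and 1370 with a variance trend and robust moderation. Full-length Notch1 and Notch1 L1601P+ΔP shared 6 genes, 5 higher and 1 lower, and 12 with a variance trend and robust moderation. Their correlation across genes was 0.462 and the shared controls alone gave 0.501, while their covariance was 0.00869 and the shared controls alone gave 0.00381.

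**Figure D4:**
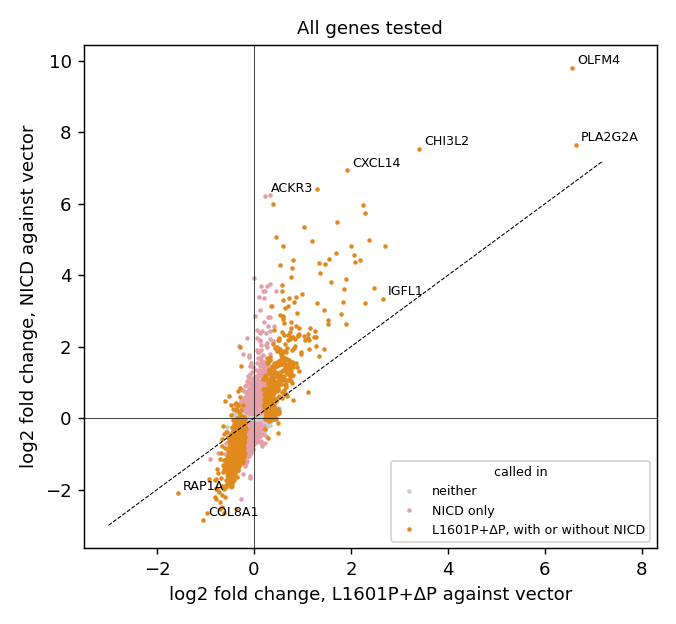
Log2 fold change of 19775 genes with Notch1 L1601P+ΔP against vector (horizontal axis) and with NICD against vector (vertical axis), 1 point per gene, coloured by the comparisons in which it was called, with a dashed line where both are equal. Among 1012 genes called with Notch1 L1601P+ΔP, 789 lay further from 0 with NICD in the same direction.

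Of the 19 genes called in opposite directions, 16 were higher with NICD and lower with Notch1 L1601P+ΔP. Their changes with Notch1 L1601P+ΔP were at most 0.60 in size. Its arrays enter both its comparison with vector and the direct one, so a chance deviation of these arrays moves both. Some of the 1012 calls with Notch1 L1601P+ΔP at an adjusted p under 0.05 are expected to be false. How many opposite calls this would give was not computed. NAP1L3 differed by 0.61 with NICD and by -0.52 with Notch1 L1601P+ΔP, PODXL, a sialomucin, by 0.83 and -0.29, and CALB1, a calcium-binding protein, by -0.43 and 0.49. NAP1L3 stood at 4.38 with vector, 3.86 with Notch1 L1601P+ΔP and 5.0 with NICD. That is below the bound of 5.67, so the test without dim genes left it out. The other 7 of the 10 with the largest difference between both forms lost the call with Notch1 L1601P+ΔP under some alternative. With NICD and Notch1 L1601P+ΔP, HIP1 differed by 1.99 and -0.30, FAM234B by 1.47 and -0.27, PTX3 by 0.49 and -0.60 and DMD by 0.75 and -0.33. LGR4 differed by 0.59 and -0.29, NEXN by 0.38 and -0.48 and SERPINB13 by -0.56 and 0.29. The highest adjusted p with Notch1 L1601P+ΔP over the alternatives was 0.0874 for HIP1, 0.574 for FAM234B, 0.0538 for PTX3, 0.664 for DMD, 0.287 for LGR4, 0.0735 for NEXN and 0.145 for SERPINB13. The NICD call of NEXN was also lost under 3 alternatives, with a highest adjusted p of 0.143. The count of 19 was 7, 9 and 10 without vector replicates 1, 2 and 3, and 11 and 7 without Notch1 L1601P+ΔP replicates 1 and 2.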

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

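The tests of RAP1A, of cell type markers and of a fixed share of responding cells were chosen after the result was seen, while that of compressed signals was chosen before.

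Probe sets with several gene symbols or none, 13522 in all, were used in no comparison of genes and are listed because some of them changed between groups. With NICD against vector, adjusted over all probe sets, 10.7% of them and 22.2% of probe sets with 1 symbol were called, a difference that was not tested and not matched on signal level. limma called 1449 of them with NICD against vector, 552 higher and 897 lower, and 168 with Notch1 L1601P+ΔP against vector. It called 1001 with NICD against Notch1 L1601P+ΔP, 115 with Notch1 L1601P+ΔP against full-length Notch1 and 1327 with NICD against full-length Notch1. With full-length Notch1 against vector limma called 0, and 784 had an unadjusted p under 0.05, which unchanged probe sets pass at a rate of 0.05. What these probe sets read was not analysed here.

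The brightest 2 of 4 RAP1A probe sets were lower with every Notch1 form. Less RAP1A mRNA would lower all 4, but the lower of the other 2 differed by 0.08 (standard error 0.05) with NICD against vector, which argues against it. Another transcript than RAP1A mRNA may be what the 2 probe sets read, since they lay at least 1.23 on the log2 scale from the others in each comparison with vector. A RAP1A isoform predicts the same values, and a transcript of the viral vector could not be tested without its sequence, so these cannot be told apart for this gene.

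Among markers of mesenchymal, endothelial and blood cells, POSTN, CD14, KDR and DCN were higher with NICD. Fibroblasts among the cells would raise their markers together, but the median log2 fold change of 6 fibroblast markers was 0.14, and COL1A1, chosen after its values were seen, stood at 7.70 with vector and 7.85 with NICD. Endothelial cells would raise theirs with KDR, but the median of 5 markers was 0.04. Monocytes or macrophages would raise LYZ and PTPRC with CD14, but the median of the 3 was 0.07, and LYZ, abundant in such cells and chosen after its values were seen, stood at 3.76 with vector and 3.83 with NICD. A change within the MCF-10A cells may account for the rises, which remains a hypothesis found and tested on the same data.

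The 125 genes at least 4-fold higher with NICD differed in how far Notch1 L1601P+ΔP moved them. On the linear scale its excess over vector was a median 8.91% of that of NICD, with most genes between 1.34% and 31.3%. It was 52.4% for PI3 and 0.2% for ACKR3, but PI3 stood at 14.63 with NICD and ACKR3 at 3.47 with vector. Such levels lie near saturation or background. At middle levels it was 57.7% for IGFL1 and 0.3% for RHOBTB3, both chosen after their values were seen. If a fixed share of the cells responded fully, all genes would give 1 share, but 67.2% of them (84 of 125) lay over 3 standard errors from it. Signals compressed near background or saturation would spare genes of middle level, taken as 7 to 12 at the common share. Of these, 68% (34 of 50) lay as far away. That share came from all 125 genes, and some genes measured lower count as middle. DAPL1, for example, stood at 5.24 with vector and 5.68 with Notch1 L1601P+ΔP. Among the middle genes the excess was a median 12.2%, with most between 2.4% and 35.7%. The middle genes thus differed too, but the test does not exclude compression. Responses that differ from gene to gene may account for these differences, as a hypothesis. A probe response that is not linear within the middle range was not tested.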

How the results depend on the processing

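Leaving out each vector array for the genes shared or opposite between comparisons was added after the data were seen, and all other alternatives were planned. Of 83 values of genes named by the size of their change, 1117 of 1145 alternative values kept direction and call, 28 lost the call and 0 reversed. Of 977 called values of named genes and list members, 117 lost the call with only the 6 arrays of 2 groups, 85 after cyclic loess, 58 with the mean of a gene's probe sets, 46 with the replicate block, 28 after median centring, 7 with array weights and 5 with a variance trend and robust moderation. Of 910 in the test without dim genes, 0 did. That test kept the values of each gene and adjusted over 12572 genes in place of 19775, so few losses were to be foreseen. Called values of dim genes were left out of it. Of 636 alternative values of the 53 list shifts, other than the estimated correlation, 605 kept the call and 31 lost it. Replicate numbers did not pair the arrays, since 1 of 18 same-number pairs correlated over 0.1 after removing group means.

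With the correlation estimated per list, the lists shifted were 2 with NICD against vector, 2 with Notch1 L1601P+ΔP against vector, 0 with full-length Notch1 against vector, 0 with NICD against Notch1 L1601P+ΔP, 2 with Notch1 L1601P+ΔP against full-length Notch1 and 2 with NICD against full-length Notch1. With a variance trend and robust moderation, the genes called were 1616 with Notch1 L1601P+ΔP against vector, 19 with full-length Notch1 against vector and 1256 with Notch1 L1601P+ΔP against full-length Notch1, and NICD and Notch1 L1601P+ΔP shared 1370 and full-length Notch1 and Notch1 L1601P+ΔP 12. Array weights gave 1638 with Notch1 L1601P+ΔP against vector and 1371 with Notch1 L1601P+ΔP against full-length Notch1. Full-length Notch1 against vector gave 3 genes with only the 6 arrays, 4 with the replicate block, and 3 lists after cyclic loess. For these and the estimated correlation the cause was not tested.

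Leaving out 1 array at a time leaves fewer samples. The genes called ranged from 4624 to 5513 with NICD against vector, 566 to 957 with Notch1 L1601P+ΔP against vector, 4 to 5 with full-length Notch1 against vector, 3010 to 3982 with NICD against Notch1 L1601P+ΔP, 403 to 642 with Notch1 L1601P+ΔP against full-length Notch1 and 4249 to 5429 with NICD against full-length Notch1. Lists ranged from 3 to 5 with full-length Notch1 against vector. Genes of opposite direction ranged from 7 to 20, those shared by NICD and Notch1 L1601P+ΔP from 512 to 945, and those shared by full-length Notch1 and Notch1 L1601P+ΔP from 4 to 6.

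With the mean of a gene's probe sets, 18 log2 fold changes reversed, and their genes are named for that reason, outside the rule for named genes. A reversal is a change of sign where the main value, the mean or both were called. Some main values lay near 0, as for PECAM1 with NICD against vector (0.02) and POLH with NICD against full-length Notch1 (0.01). Some of the means given here did as well, as for LATS2 and ACTA2. With NICD against vector these were DLL1 (-0.43), LATS2 (-0.014), DNAJC3 (-0.14), MVK (-0.15) and PECAM1 (-0.21), and with Notch1 L1601P+ΔP against vector MMP2 (0.19). With NICD against Notch1 L1601P+ΔP they were POLH (-0.22), TAGLN (0.575), MYL9 (0.85), MMP2 (-0.19), LATS2 (-0.005) and DNAJC3 (-0.13). With NICD against full-length Notch1 they were NOTCH1 (-0.086), DLL1 (-0.26), POLH (-0.23), ACTA2 (-0.007), TAGLN (0.67) and DNAJC3 (-0.19). Signals near background limit the small changes among dim genes, and 7203 genes lay below the bound of 5.67.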

Other observations

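The test of direction at equal size and the regroupings of arrays were chosen before their results were seen, while the other settings of the first, the rotations of array deviations, and the listing of genes with an extreme in Notch1 L1601P+ΔP and of families by name were chosen after.

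With Notch1 L1601P+ΔP, 35 genes were higher and 36 lower than with both vector and NICD, called in both comparisons. Both use the same Notch1 L1601P+ΔP arrays, so a chance deviation of these moves both the same way, and no count for unchanged groups was computed. Where full-length Notch1 stood for these genes as a set was not analysed here. The cytokine IL1B, chosen after its values were seen, stood at 8.42 with vector, 9.22 with Notch1 L1601P+ΔP and 8.93 with NICD. Its call between Notch1 L1601P+ΔP and NICD ended without Notch1 L1601P+ΔP replicate 2 or NICD replicate 3, with a highest adjusted p of 0.0786. PTX3, a secreted pattern recognition protein, stood at 7.50, 6.90 and 7.99, and its call with Notch1 L1601P+ΔP was also lost under an alternative (highest adjusted p 0.0538). Among families by the stem of the gene symbol, none passed a one-sided Fisher's exact test for genes at least 2-fold changed with NICD, and the smallest adjusted p was 0.265, for 5 collagens among the 354 higher genes.

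Among genes called with NICD against vector and changed by 1 to 2 on the log2 scale, the log2 fold change with Notch1 L1601P+ΔP was divided by that with NICD. The median ratio was 0.309 for 190 lowered genes and 0.27 for 229 raised genes. The difference of 0.039 lay under the bound of 0.1 set for it. It was 0.009 after cyclic loess, 0.054 after median centring and between 0.016 and 0.056 when 1 array was left out. A dependence on direction as large as the hypothesis required was therefore not seen, and a smaller one stays open, since genes on the same arrays are not independent. With Notch1 L1601P+ΔP, 150 of the lowered and 117 of the raised genes were called in the same direction, and the difference between these counts was not tested.

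Regrouping the 6 arrays of 2 groups gives 10 splits, too few for a share under 0.05. In each of the 6 comparisons, 1 split, the real one, gave as many genes, and the highest other gave 0 by limma. The real counts were 5460, 1012, 7, 3923, 735 and 5346. Where 2 groups differ in many genes, the other splits mix them and widen the spread, so few calls there were to be foreseen. For lists, 1 split gave as many with NICD against vector (8, highest other 5), full-length Notch1 against vector (5, highest other 3), NICD against Notch1 L1601P+ΔP (10, highest other 8), Notch1 L1601P+ΔP against full-length Notch1 (10, highest other 8) and NICD against full-length Notch1 (11, highest other 6). With Notch1 L1601P+ΔP against vector 2 splits did, with 9 in the real one and 12 in the highest other. Mixed groups thus also gave shifted lists with the preset correlation, so a number of lists shifted does not by itself show a difference between groups.

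Of 100 splits of 9 arrays, 1 gave as many genes of opposite direction (19, highest other 0) and 1 as many shared by full-length Notch1 and Notch1 L1601P+ΔP (6, highest other 1). In these draws, the real split alone kept the groups whole, and mixing groups that differ widens the spread within them, so the splits do not exclude chance for either count. For genes shared by NICD and Notch1 L1601P+ΔP, 4 splits gave as many as the real 884, with 3153 in the highest other. The other 3 kept the NICD arrays together as the reference, so they carry the difference of NICD from the rest, which points to a structure of the samples. That share lies at the edge of 0.05, and it was not under it while a split and its mirror were counted apart, a choice changed after the result was seen. The splits therefore decide nothing for that count, but the covariance across genes was 0.0578, where 100 rotations of the arrays' own deviations, as for unchanged groups with the same controls, gave at most 0.0067. The correlation of 0.712 also exceeded their highest of 0.655, which argues against chance for NICD and Notch1 L1601P+ΔP. For full-length Notch1 and Notch1 L1601P+ΔP the covariance of 0.00869 exceeded all 100, while 76 had a correlation as high as the real 0.462. That correlation spans all 19775 genes and does not decide on the 6 shared ones. Independent lists would share 0.1 higher and 0 lower genes. That expectation takes no account of the shared vector arrays. The simulations, which took genes as independent, shared 0 on average. In them both groups were unchanged, so few calls and few shared genes were to be foreseen. These values therefore do not decide on the 6 genes as a set. The limma adjusted p with full-length Notch1 against vector was 2.18e-10 for PLA2G2A and 3.48e-06 for OLFM4. Among the 6, the calls of HSD17B2, SERPINA3 and CCN1 with full-length Notch1 ended under some alternatives. For genes of opposite direction no rotations were run.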
